A study of Halobacterium salinarum NRC-1 with 8 samples.

How the data were processed

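Spot intensities of 8 2-colour arrays were used as deposited: per the file headers, each holds linear brightness of 10752 spots and of their local background in the Alexa 532 and Alexa 647 channels, each scanned at a higher and a lower gain. The high-gain mean intensities and median backgrounds were used. The deposited table of processed values is on a log10 scale. Set against the scanner values, it matched the log10 ratio of Alexa 532 over Alexa 647 without background subtraction plus 1 constant per array, within 0.005 for 84.2 to 96.6% of spots (Pearson r 0.834 to 0.987 over spots), and it is not turned to culture over reference. Its column medians were 0.045 to 0.142. Of saturated spots 99.5% differed by more, of other spots under 1.5 times background in a channel 4.37%, and of the rest 6.58%. What was done to them stays unknown, and the quantification software is not given in the sources used here.

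Dye directions come from the labels: the culture was in Alexa 532 on replicate 1 and in Alexa 647 on replicate 2 of each condition. Dye orientation coincides with 2 series of arrays and is balanced over the conditions. Backgrounds were corrected with normexp (offset 50), ratios normalised within each array by loess and turned to culture over reference. The 4 spots of a feature were averaged, giving 2688 features, and the 2 arrays of a sample were averaged. limma 3.58.1 in R 4.3.3 fitted oxygen and light as additive effects to the 4 sample values, with 1 residual degree of freedom (moderated by a prior of 3.68 degrees of freedom and SD 0.149). The intercept, with centred codes, is the comparison with the reference. Adjusted p-values are limma's moderated test with Benjamini-Hochberg adjustment over features, at 0.05. Gene lists, fixed before the data were examined, were tested with camera at a preset correlation of 0.01, adjusted over the 7 lists with 3 or more measured members. Of 22 lists, 8 had no named member and 7 had 1 or 2. The oxygen by light difference was set against the spread between dye-flipped arrays from a fit to 8 arrays with dye orientation as a covariate.

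A feature counts as above background on an array where its mean ratio of spot to local background is 1.5 or more, a limit chosen after seeing the data. A side with no such array is called not well above background, and 13 of 133 named genes had no such array in the culture channel. Lower bounds compare the mean of the bright side with that of the dim side, each dim value raised to the lowest signal above background on its array, per channel after loess and Aquantile normalisation, and they are open to dye bias. The bounds of folP (1.57-fold) and gyrB (1.33-fold) against the reference exceeded their ratios on the arrays where the culture was above background, so they are not used as folds, and those of other named genes gave no fold. Saturated spots were kept. They numbered 100 to 171 per array in Alexa 532 and 150 to 314 in Alexa 647.

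Gene names came from the table given for the deposited probes: 532 probes carry 1 symbol (133 genes), 0 several, and 10220 are unnamed here. All 133 symbols occur in the RefSeq gene table given, which is of another strain (assembly ASM479960v1), so no coordinates are given. The named genes were, per comparison, the 10 largest differences on each side among genes past the threshold with 1 sign in both pairs (in all samples for the reference) and both dye orientations, filled up with such genes at an unadjusted p under 0.05. To these came VNG0019H and ura3, up to 4 members of each list with a camera call or 3 members past the threshold, and for the oxygen by light difference the 5 largest on each side beyond 3 times the spread. The rule was applied to named genes, with at most 2 unnamed features per side. Transposases were to be left out.

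The deposited table leaves 594 to 645 spots blank per array, in 319 features. No reason is given in the sources used here. These spots were kept. Leaving them out was tried as an alternative after the results with all spots had been seen. The procedure was tested on simulated data with 200 of 2688 features changed. Variances were drawn from the fitted prior, with independent array noise and a constant dye effect. No oxygen by light effect and no background floor were simulated, so the rates below hold only under those settings. For the oxygen effect it called 11.9% of changes of 0.5 on the log2 scale, 76.1% of 1 and 98.5% of 2. For the light effect it called 13.4, 83.6 and 100%, and for the reference 82.1, 100 and 100%. False calls were 4.62, 7.09 and 3.59% of all calls. Alternatives covered background, normalisation, spot averaging, dim features, dye orientation, array-level fitting, variance moderation, covariates, the deposited table and each array left out. Precision is limited by the number of arrays and by the weak Alexa 532 signal.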

Results

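The series measured RNA of Halobacterium NRC-1, a halophilic archaeon, in a strain lacking the gene vng19h and the ura3 marker gene. Cultures grew in light or in dark, each at high oxygen (shaken at 210 rpm) or at low oxygen (100 rpm in a stoppered flask). Each of the 4 conditions had 1 RNA sample, hybridised on 2 arrays with the dyes exchanged against a common reference RNA of the NRC-1 strain in standard growth. The 2 arrays of a sample count as 1 replicate, so n = 1 per condition. The error of the fit is the oxygen by light difference of these 4 samples, moderated over all features. The p-values and standard errors (SE) therefore do not measure a spread between replicates. In the Alexa 532 channel 13.3 to 32.1% of spots per array reached 1.5 times their local background, and in the Alexa 647 channel 53.3 to 69.3%. Of the 133 genes with a name, 36 reached that level in the culture channel on all 8 arrays and 13 on none.

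The targeted genes were examined first, because they bear on the strain labels. No probe named here belongs to VNG0019H, so its level is not analysed here. The gene pyrF encodes orotidine 5'-phosphate decarboxylase, the activity of the ura3 marker, and was taken as that gene. Its ratio of culture over reference was below 0 on 8 of 8 arrays, with sample means of -0.88 (high oxygen, light), -0.74 (high oxygen, dark), -0.53 (low oxygen, light) and -0.70 (low oxygen, dark) on the log2 scale (adjusted p = 0.0146). The mean over samples was -0.71, and it shrank to -0.26 without background subtraction and to -0.43 in the deposited table's values. pyrF was not well above background in either channel, so no fold is given and it checks the labels only weakly.

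The comparison of low with high oxygen asks which transcripts respond to oxygen supply in the knockout strain. Genes for sensory rhodopsins, their transducers and chemotaxis steer swimming in response to light and chemical signals. As a group they had lower estimates at low oxygen, with a median log2 difference of -0.221 (camera, adjusted p = 0.00217). Of the 13 measured members 11 were lower, and 6 in the deposited table's values. Camera sets the members against the other features, so its p-value does not measure a spread between samples. The list had adjusted p = 0.859 with an estimated correlation. That estimate was -0.0256, below the preset 0.01, and rested on 1 residual degree of freedom. It therefore does not decide whether correlation between members matters. The transducer genes htr4, htr18, htr8 and htr7 had differences of -0.48 ± 0.18, -0.42 ± 0.13, -0.36 ± 0.16 and -0.30 ± 0.13 (SE). Those of htr4, htr18 and htr8 were -0.89, -0.77 and -0.61 with the culture in Alexa 532 and -0.08, -0.06 and -0.11 with it in Alexa 647, and they were above background on 2, 1 and 2 of 4 low-oxygen and 2, 2 and 3 of 4 high-oxygen arrays. The chemotaxis genes cheA, cheR and cheY, above background on every array, had -0.27, -0.28 and -0.21 (cheY saturated on 2 of 4 high-oxygen arrays). cheR was only 1.73 (light) and 1.68 (dark) times background on the low-oxygen arrays with the culture in Alexa 532. By contrast, cheB, htr1, htr2 and sop2 lay between -0.02 and 0.02. The list median was -0.212 in the light pair and -0.220 in the dark pair. No member passed the test on its own, over all features or adjusted over the list alone. The median was -0.096 without background subtraction (adjusted p = 0.0116) and -0.147 without the Alexa 532 array of the low-oxygen dark sample (adjusted p = 0.0331). The list also missed the threshold with median centring (median -0.125, adjusted p = 0.542), in the arrays with the culture in Alexa 647 (-0.077, adjusted p = 0.709), without the Alexa 532 array of the high-oxygen dark sample (-0.173, adjusted p = 0.0503), and in the deposited table's values, where the median was 0.0018.

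**Figure D1:**
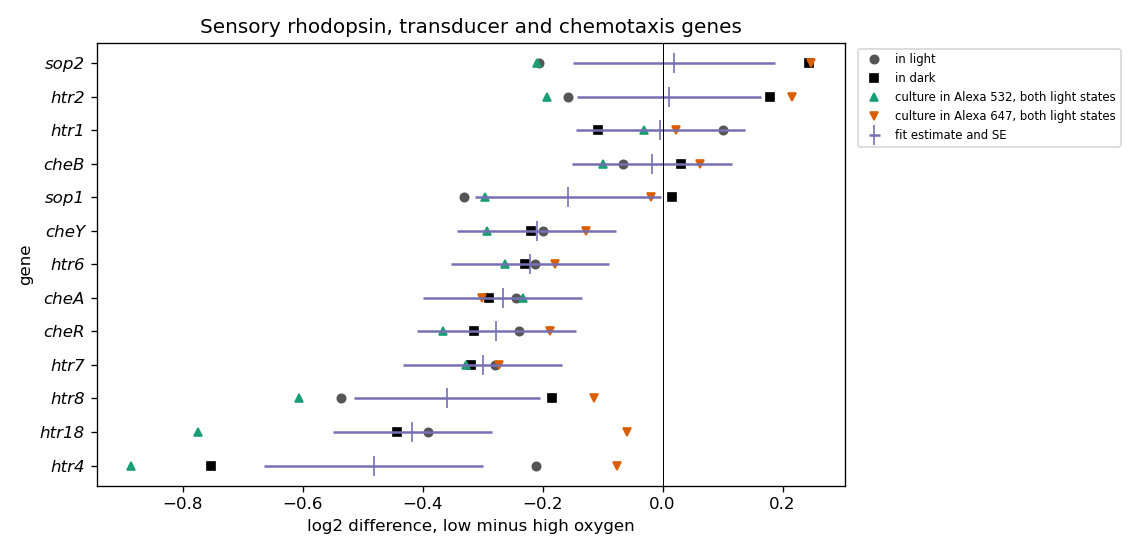
Log2 difference between low and high oxygen (x axis) for the 13 measured genes of the sensory and chemotaxis list (y axis), with circles and squares for the pairs in light and in dark, triangles for the 2 dye orientations, and bars for the fitted estimate with its standard error. The points with the culture in Alexa 532 (median -0.292) lie further below 0 than those with the culture in Alexa 647 (median -0.077).

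No single gene passed the threshold for oxygen (limma, 0 of 2688 features, of which 263 had an unadjusted p under 0.05 where 134 are given by chance). The largest well measured estimate among named genes was that of gdhA1, a glutamate dehydrogenase gene, 1.68-fold higher at low oxygen (log2 0.75 ± 0.14 SE, 0.83 in light and 0.68 in dark, adjusted p = 0.466). It was above background on 4 of 4 low-oxygen and 2 of 4 high-oxygen arrays. The gene rpl12p of ribosomal protein L12 was 1.42-fold higher (log2 0.51 ± 0.19, adjusted p = 0.491), purM of purine synthesis 1.40-fold and endA of tRNA splicing 1.32-fold higher, the last 2 above background on 2 of 4 low-oxygen and 1 of 4 high-oxygen arrays. purM had 0.83 with the culture in Alexa 532 and 0.15 with it in Alexa 647, and endA 0.10 and 0.71. The genes dcd (0.89), mch (0.64), cysS (0.52) and glpK (0.45) had positive log2 differences but were not well above background at high oxygen, and their bounds gave no fold. hutU (0.36) was not well above background on either side. On the other side stood msrA, a methionine sulfoxide reductase gene (log2 -0.46 ± 0.13), carA of carbamoyl phosphate synthesis (-0.42 ± 0.13) and the tRNA synthetase gene pheS (-0.36 ± 0.13), each above background on 2 of 4 arrays per side, those with the culture in Alexa 647. There msrA had -0.03, against -0.89 with the culture in Alexa 532. None of these 12 named genes passed the test, and mch, hutU and msrA changed sign in the deposited table's values.

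The other lists did not pass for oxygen. All 5 genes of central carbon oxidation had estimates at or above 0 (median 0.080, adjusted p = 0.606). Of the 7 purine synthesis genes 5 were higher (median 0.074, adjusted p = 0.606), and of the 5 pyrimidine synthesis genes 3 (median 0.014, adjusted p = 0.695). DNA repair (median 0.135, adjusted p = 0.606), chaperones and proteasome (0.0036, adjusted p = 0.981) and cobalamin synthesis (-0.00086, adjusted p = 0.895) had 4 members each. The mean of the pyrimidine list was -0.063, opposite to its median, and camera put the chaperone list on the lower side with a mean of 0.020. Smaller lists were not tested. The arginine fermentation genes arcA and arcC had 0.10 and -0.13, and the respiratory genes nuoL and sdhC 0.16 and -0.11. In the list of bacteriorhodopsin, halorhodopsin and carotenoid synthesis, bat had 0.22 and hop -0.14. bat was above background on 0 of 4 low-oxygen and 1 of 4 high-oxygen arrays. The molybdopterin genes moaA and moaC had -0.03 and -0.28, and phoU 0.12.

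The comparison of dark with light asks which transcripts respond to illumination. No feature passed the threshold (limma, 0 of 2688, with 152 at an unadjusted p under 0.05 and 134 given by chance). Among named genes purM was 1.43-fold higher in dark (log2 0.52 ± 0.13 SE), moaA of molybdopterin synthesis 1.44-fold (0.53 ± 0.15, but 0.09 with the culture in Alexa 532) and hisD of histidine synthesis 1.38-fold (0.47 ± 0.14). The triosephosphate isomerase gene tpiA was lower (-0.38 ± 0.13). All 4 had an adjusted p of 0.827 and were above background on 1 or 2 of 4 arrays per side, and hisD and tpiA changed sign in the deposited table's values. mch (0.39) was not well above background in light, and hutI (0.48) and gatC (-0.81) on neither side. Of the 13 sensory and chemotaxis genes 9 were lower in dark (median -0.028, adjusted p = 0.994). Of the 7 purine synthesis genes 6 were higher (median 0.032, adjusted p = 0.338). The pyrimidine (0.082, adjusted p = 0.623), central carbon (0.077, adjusted p = 0.623), DNA repair (-0.104, adjusted p = 0.994), chaperone and proteasome (-0.044, adjusted p = 0.994) and cobalamin (0.030, adjusted p = 0.994) lists did not pass, and no member did adjusted over the list alone. Camera put the chaperone list on the higher side, opposite to its median and mean (-0.020).

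Against the reference pool, the knockout cultures had lower RNA of purF, which encodes the enzyme that opens purine synthesis, by 1.67-fold (log2 -0.74 ± 0.08 SE, 4 of 4 samples, adjusted p = 0.0164). RNA of pheS was 1.46-fold lower (-0.54 ± 0.07, adjusted p = 0.0183) and that of panB, of pantothenate synthesis, 1.35-fold lower (-0.43 ± 0.07, adjusted p = 0.0284), with -0.12 on the arrays with the culture in Alexa 532 and -0.74 on the others. purF and pheS were above background on 4 of 8 arrays in the culture channel and on the other 4 in the reference channel, each time in Alexa 647, so no array measured both sides. trpC of tryptophan synthesis was 1.27-fold higher (0.35 ± 0.07, adjusted p = 0.0477), above background on 1 of 8 arrays in the culture channel and 2 of 8 in the reference channel, and was at -0.0016 in the deposited table's values. folP of folate synthesis (log2 0.95, adjusted p = 0.00901) and the gyrase gene gyrB (0.81, adjusted p = 0.0228) were also higher. Their culture channel was above background on the 4 Alexa 647 arrays alone, and their reference channel on 0 arrays. On those 4 arrays folP had 0.61 (limma, adjusted p = 0.00854) and gyrB 0.28 (adjusted p = 0.18). The dye effect does not cancel there, and 1062 of 2688 features passed. purB (log2 0.88, adjusted p = 0.0152) was not well above background. The spots of folP, gyrB, purB and phoU are among those blank in the deposited table on some arrays. No other of the 133 named genes has such a spot, and these 4 are among the 5 named genes called higher, with trpC. Over all features, 41 of the 284 calls and 319 of 2688 features have one. phoU (0.45) and aroC (-0.37) also passed but differed in sign between dye orientations. Without background subtraction the log2 differences of purF and pheS were -0.29 and -0.25, both past the threshold, and trpC (0.027) did not pass. In the deposited table's values purF was at -0.23 and panB at -0.24, both past the threshold, and pheS (-0.12) did not pass. Strain and growth conditions differ together here, and the reference has no spread of its own.

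**Figure D2:**
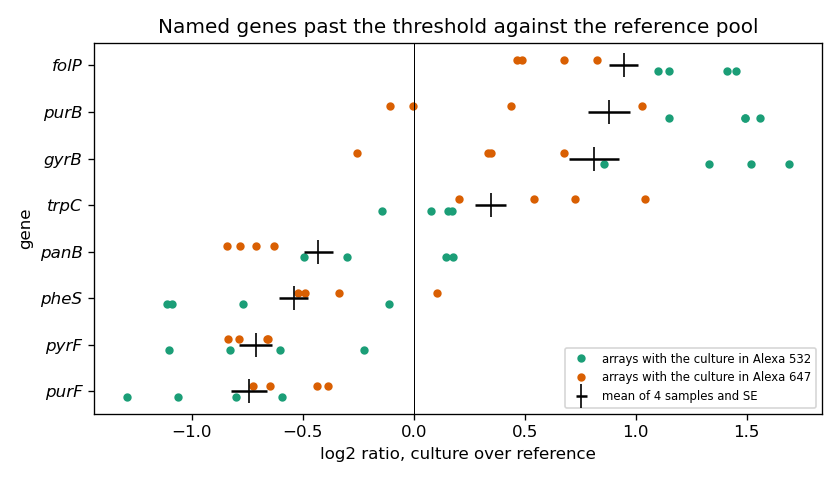
Log2 ratio of culture over reference (x axis) for the 8 named genes (y axis) past the threshold with 1 sign in all samples and both dye orientations. Each array has a point coloured by the dye of the culture. Black bars give the mean of the 4 samples with the standard error of the fit, which is not their spread. purF and pyrF lie below 0 on all 8 arrays, and folP above 0 on all 8.

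In all, 284 of 2688 features differed from the reference (128 higher, 156 lower), of which 225 had 1 sign in all samples and both dye orientations. Named genes that did not pass included arcC (0.27), argH (0.26), htr18 (0.22), hemL (-0.32), glmS (-0.32), pan1 (-0.27), serS (-0.27), tpiA (-0.27) and dnaK (-0.26). Among features of 1 sign above background on at least 1 array per side, the largest losses were in 2 without a name here. They were at probe 1911 (log2 -3.38 ± 0.09) and probe 1547 (-2.25 ± 0.07). Their culture channel was above background on 2 and 3 of 8 arrays, and their reference channel on 8 and 7. The sizes of these losses are therefore not well measured. The purine list had 2 of 7 members past the threshold (median 0.026, adjusted p = 0.736) and the pyrimidine list 1 of 5 (median 0.082, mean -0.071, on the higher side in camera, adjusted p = 0.908), with the same counts adjusted over the list alone. The chaperone and proteasome list had 0 of 4, and 1 adjusted over the list alone (median -0.135, adjusted p = 0.626). The sensory (0.060), central carbon (-0.079), DNA repair (-0.071) and cobalamin (-0.027) lists had adjusted p = 0.736 each. The count fell to 14 without the Alexa 532 array of the high-oxygen dark sample, where folP alone of the 8 named genes with 1 sign passed, to 177 without the Alexa 647 array of the low-oxygen light sample and to 0 of 1117 features tested with plain background subtraction, panB being the only 1 of the 8 tested there (-0.97, adjusted p = 0.416), and was 132 when the 319 features with a blank spot were left out.

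The last comparison asks whether the effect of oxygen differed between dark and light, and has no test between samples. Among named genes 4 exceeded 3 times the spread between dye-flipped arrays. The ribosomal protein gene rpmC had an oxygen difference of -0.05 in light and 1.16 in dark. The glycyl-tRNA synthetase gene glyS had 0.79 in light and -0.32 in dark, and gyrB 0.25 and -0.53. trpB had -0.996 and 0.47 but was not well above background in any condition. Without background subtraction the differences between dark and light shrank from 1.47 to 0.42 for trpB, from 1.21 to 0.41 for rpmC and from -1.11 to -0.35 for glyS, and gyrB went from -0.78 to -0.38 with median centring. Over all features 85 of 2688 exceeded the limit of 3 times the spread, a share near that of the 4 among 133 named genes.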

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

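The genes below were flagged because their oxygen difference in dark and in light differed by over 3 times the spread between dye-flipped arrays. The signs in dark and light were also opposite, with rpmC near 0 in light (-0.05). They are 4 of 133 named genes, a share near that over all features (85 of 2688). How many chance would give was not estimated. With 1 sample per condition the difference was not tested. The dark value minus the light value was 1.47 for trpB, 1.21 for rpmC, -1.11 for glyS and -0.78 for gyrB on the log2 scale. Without background subtraction these were 0.42, 0.41, -0.35 and -0.65, and gyrB was at -0.38 with median centring. trpB was not well above background in any condition, and gyrB has blank spots in the deposited table. In the culture channel glyS and gyrB stayed under 1.5 times background on every array with the culture in Alexa 532. rpmC did so on all of these but that of the low-oxygen dark sample. No sample stood far from the others among the 17 genes named for the reference comparison.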

How the results depend on the processing

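No pairing was possible, since each condition has 1 RNA sample on dye-flipped arrays. Causes were not tested unless stated. The count of features that differed from the reference was 0 of the 1117 features tested with plain subtraction (with 55 of the 284 calls), 582 with median centring, 578 with the median over spots, 1394 and 1062 with only the Alexa 532 or only the Alexa 647 culture arrays (where the dye effect does not cancel), 818 with 8 arrays and the sample as a random block (consensus correlation -0.25, so 2 arrays of a sample count for more than independent ones), and 548 with a trend and robust moderation. Single arrays left out gave 14 to 420. Leaving features with a blank spot out gave 132, although 243 of the 284 calls lie outside those features, and named genes alone gave 23 when refitted (8 with the p-values of the full fit adjusted over them), all chosen after seeing the data, as was leaving blank spots out (402 calls, 247 of them shared with the 284). The oxygen effect had 4 calls with the random block, 4 with trend and robust moderation and 12 with the deposited table's values. gdhA1 was higher at low oxygen in 24 of 24 alternatives with a test and passed in 2 of them, with the block (adjusted p = 0.0364) and the deposited table (0.0167), against 0.466 on means. Each array left out gave 0 calls for oxygen, and light had 0 under every alternative run. Lists called over the 3 comparisons numbered 2 without background subtraction and with the deposited table, 0 with median centring, with only Alexa 647 culture arrays and with an estimated correlation, and 0 to 1 with an array left out. The sensory and chemotaxis list passed in 19 of 24 alternatives with a test (adjusted p from 0.000327 to 0.928). It did not pass with median centring (-0.125), only Alexa 647 culture arrays (-0.0766), an estimated correlation (-0.221, adjusted p = 0.859) or the deposited table (0.00183), nor without the Alexa 532 array of the high-oxygen dark sample (-0.173, adjusted p = 0.0503), and ranged from -0.269 to -0.147 with an array left out. With blank spots left out its adjusted p was 0.0438. Its median was -0.0957 without background subtraction. The oxygen by light difference counted 54 features without background subtraction. pyrF was below 0 on 1 array with plain subtraction, which leaves out spots at or below background.

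Signs turned for single genes, none past the threshold there. With the deposited table these were, against the reference, trpC (-0.0016), glmS (0.056) and pan1 (0.112), for oxygen mch (-0.027), hutU (-0.040), msrA (0.076), htr7 (0.033) and pyrF (-0.344), and for light hisD (-0.147) and tpiA (0.070). glmS was 0.0094 without background subtraction and 0.053 with plain subtraction. The oxygen difference of pyrF was -0.079 without background subtraction and -0.154 with only Alexa 647 culture arrays. Its light difference was 0.016 with scaling between arrays, 0.134 with the median over spots, 0.025 with only Alexa 647 culture arrays, 0.139 within high oxygen, and -0.201 to 0.176 with single arrays left out (0.150, 0.059 and 0.033 among the others). Against the reference, of the 8 named genes called with 1 sign, trpC (0.027) was lost without background subtraction, trpC (0.066) and panB (-0.12) with only Alexa 532 culture arrays, purB (0.34), gyrB (0.28) and pheS (-0.31) with only Alexa 647 culture arrays, and trpC and pheS (-0.12) with the deposited table, where purB and gyrB were not tested. Plain subtraction tested panB alone of the 8, and its difference grew to -0.97 without passing (adjusted p = 0.416). Without the Alexa 532 array of the high-oxygen dark sample all but folP were lost (adjusted p from 0.0574 for purF to 0.113 for trpC). trpC was also lost without each of 4 other arrays and without features with a blank spot, and panB without the Alexa 647 array of the low-oxygen light sample (adjusted p from 0.0538 to 0.0864).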

Other observations

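The tests of single dye orientations, of members above background on all arrays and of dye labels were chosen after their results were seen. The tests of matched lists and of pyrF were written before, and the matched lists under 2 further settings were added after.

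The sensory and chemotaxis list was lower at low oxygen with the preset correlation, and did not pass with an estimated one (camera, adjusted p = 0.859). The estimate was -0.0256, below the preset 0.01, and rested on 1 residual degree of freedom. That result therefore does not decide whether correlation between members matters. The 4 members above background on all arrays, cheA, cheB, cheR and cheY, had a median of -0.238, with cheB at -0.018. The SE of 0.0755 is over genes, which are not replicates. These values cover only those 4 genes. For htr4, htr18 and htr8 the differences were -0.89, -0.77 and -0.61 with the culture in Alexa 532. With it in Alexa 647 they were -0.08, -0.06 and -0.11. Whether signal near the background carries the shift of the dimmer members stays open. Arguing against a trend with signal strength, the list median lay at percentile 0.19 of 10000 random lists matched on mean intensity. It lay at 0.33 with median centring. The random lists were drawn feature by feature, so correlation between members is left out. In the deposited table's values the list had no shift (median 0.00183), and its percentile of 7.93 does not argue against such a trend. A constant dye effect cancels in this contrast, but whether the arrays of 1 orientation carry the shift stays open, with a median of -0.0766 (SE 0.058) in the weaker orientation and -0.292 in the other. Oxygen supply, which the design names, was not tested apart from shaking speed and the stopper.

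After turning, the mean ratios of the 2 dye orientations correlated at -0.623 over 2688 features (-0.241 over the 357 above background on all arrays), so a dye effect of each feature may exceed the difference between culture and reference. Wrong dye labels in 1 array series would turn the oxygen contrasts of that series, but the contrasts of the 2 orientations correlated at 0.408 in light and 0.723 in dark over those 357 features, and at 0.084 and 0.176 over all features. These correlations are across features, which are not independent replicates. No biological explanation was tested.

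The low ratio of pyrF may reflect the deleted marker. It lay at percentile 0.5 of the 200 features nearest in signal over background, whose median was 0.062. Because pyrF was above background on none of the arrays in either channel, this does not exclude a shift shared by equally dim features, and the limit set before for this test was wrong for so weak a gene. That explanation and the absence of the gene from the strain, which the labels state, both stay open.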
